A study of Homo sapiens with 6 samples.

How the data were processed

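RNA was sequenced from RKO cells, an established human colorectal carcinoma cell line, after 48 h in control medium (3 samples) or in fasting medium (3 samples). Per the labels' treatment field, control medium held 10% serum and 4.5 g/L glucose, and fasting medium held 1% serum and 1 g/L glucose. Groups were taken from each sample's treatment label, because the shared protocol text describes the low-serum medium for all samples. Per the labels' protocols, total RNA was extracted on columns and made into strand-specific libraries. The series' design text also names drug treatments, which were not analysed here. Nothing in the labels says whether the 3 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

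The submitters' processing notes name UMI-tools 1.0.0, HTSeq 0.6.1 and DESeq 1.10.1, with no role or order. The aligner, genome build and annotation are not given in the sources used here, so no coordinates are printed. Whether counting used the strand is not given either. One deposited table served all samples. Its 6 deposited sample columns name no unit. From the values, they hold normalized read counts, a signal that equals the reads of each gene divided by a size factor per library, as the authors left it. The same table holds the authors' log2 fold change, p-value and adjusted p-value for each gene. The authors' log2 fold change equalled the log2 ratio of the group means within 1.04e-09, apart from genes with no read in one group, where it is infinite.

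The deposited table listed 3511 genes, and the highest adjusted p in the authors' deposited table was 0.04999. Adjusted p, rank and p together gave 29845 genes tested by the authors, of which the table holds 11.8%. The table was thus selected on the outcome. No library total, no share of all reads and no enrichment against all expressed genes could be formed from it. A gene outside the table is described only as not listed. No value for it was used here.

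The normalized counts were whole multiples of the worth of 1 read for 100% of values in each library, within a tolerance of 0.01 read. This gave size factors of 1.01, 1.41 and 1.38 for control replicates 1 to 3 and 0.788, 0.956 and 0.727 for fasting replicates 1 to 3. The planned design had foreseen edgeR for read counts and limma for values such as FPKM or CPM, and the deposited signal is neither. After the unit was seen, limma was chosen for the values as deposited, and edgeR on the recovered reads became an alternative. The main test was thus limma, with a mean-variance trend and empirical Bayes moderation, on log2(normalized count + 1), for genes with a mean of at least 1 in one group. All log2 fold changes are fasting minus control on the log2(normalized count + 1) scale, which understates the change of low genes, and fold values are taken from them. Fold values thus compare means of log2 values and differ from ratios of the printed group means. Benjamini-Hochberg adjustment counted all 29845 genes the authors tested, with unlisted genes at p = 1, and 0.05 was the threshold. Tests were two-sided. The moderation was estimated on the listed genes alone, which were chosen for their difference.

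Gene lists were fixed before the data were examined, 37 in all, and matched by Ensembl identifier. Symbols came from a table of gene names, which held 3467 of the 3511 identifiers. It was also used in place of 7 symbols that a spreadsheet had turned into dates. A single list symbol, an older name of another member, had no match. Lists with at least 5 listed members (30 lists) were compared with the other listed genes by camera (limma, preset correlation 0.01), with adjustment over these 30 lists, and again with an estimated correlation and with fry. Since camera compares a list with other listed genes alone, it says how its listed members stand among genes that had already been called by the authors.

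The genes named in the text follow a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among called protein-coding genes whose groups did not overlap, the 2 members of each list with the smallest adjusted p and the first one of the opposite direction past the threshold, and 16 genes whatever their result. Some genes that the rule names are not reported here. The planned minimum of 5 CPM for the first part had no counterpart in this unit and was replaced, after seeing the unit, by a mean of at least 100 normalized counts in the higher group. Other list members are named as examples, chosen after their values were seen.

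Alternatives covered other pseudocounts, filters, tests and scalings, count tests on the recovered reads (edgeR, DESeq2 and limma-voom), thinned reads, a replicate block, leaving out each library, and removal of a trend with transcript length. Transcript lengths were those of the longest protein-coding transcript, or otherwise the longest transcript, in GENCODE annotation, and 98.7% of listed genes had one. It may not be the annotation the authors used, and no coordinates were taken from it. The gene tests of limma and edgeR were checked on simulated data for 3416 of the listed genes, while DESeq2, limma-voom and fry were not tested on simulated data. In the simulated comparison limma recovered 82.1% of 1.5-fold changes, 89.6% of 2-fold changes and 100% of 4-fold changes, with 0 false calls. edgeR recovered 80.6%, 89.6% and 100%, also with 0 false calls. The simulation drew all libraries with 1 common dispersion taken from the controls, without the spread or length trend of fasting replicate 3 described below. In it only 67, 67 and 66 genes changed by 1.5-fold, 2-fold and 4-fold, so its rates do not describe the tests on the real libraries. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.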

Results

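RKO colorectal carcinoma cells were compared after 48 h in fasting medium (1% serum, 1 g/L glucose) and in control medium (10% serum, 4.5 g/L glucose), with 3 libraries each. The table lists 3511 genes that the authors had called. Reads in these genes numbered 4017618, 5602177 and 5513396 in control replicates 1 to 3 and 4187326, 5071791 and 4389842 in fasting replicates 1 to 3. Total depth is unknown, since only listed genes are covered. The chi-square per gene, 1 for sampling noise alone, was 2.17, 5.14 and 6.70 between pairs of control replicates and 1.90 between fasting replicates 1 and 2, but 58.5 between fasting replicates 1 and 3 and 57.9 between fasting replicates 2 and 3.

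Fasting replicate 3 stood apart by transcript length. Among transcripts of 78 to 2383 bases its values lay a median of 0.41 log2 units above the mean of the other fasting libraries, and among those of 5165 to 22743 bases they differed by -0.46. The Spearman correlation of this difference with transcript length, across 2886 genes of at least 100 normalized counts in one group, was -0.722 (95% bootstrap interval -0.743 to -0.700). For control replicate 1 against the other controls it was -0.0188. Genes are not independent replicates, so these values describe the libraries.

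**Figure D1:**
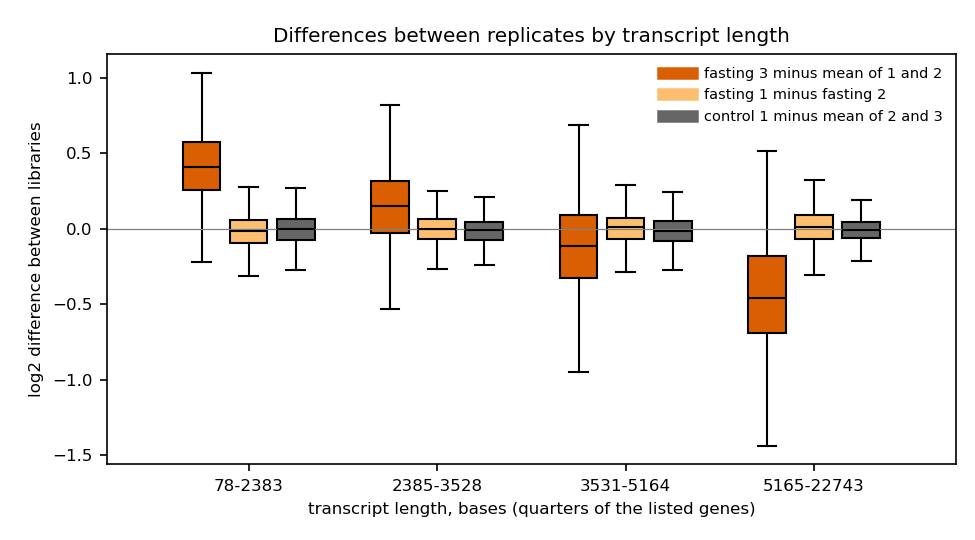
Differences between replicate libraries (log2 units, vertical axis) in 4 equal bins of genes by transcript length (bases, horizontal axis), for listed genes with at least 100 normalized counts in one group. Boxes span the quartiles with the median as a line, whiskers reach at most 1.5 box lengths, and points beyond are not drawn; the medians for fasting replicate 3 run from 0.41 in the shortest bin to -0.46 in the longest.

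In fasting medium, all listed members of the heat shock (15 of 16), NRF2 target (12 of 28) and ATF4 target (26 of 34) lists rose, and 54 of 55 listed genes of DNA replication and mitosis fell. With an estimated correlation none of these lists passed against the other listed genes (adjusted p = 0.299, 0.109 and 0.109, and 0.0502 for both cell cycle lists). All 10 listed genes of a stress and RNA quality list rose as well. HSPA6 (ENSG00000173110), a stress-inducible HSP70 chaperone, went from 11.5 ± 2.4 to 4617 ± 739 normalized counts (SD, n = 3 each). By the means of log2 values, as for all folds here, the rise was 371-fold. HMOX1 (ENSG00000100292), which encodes the haem-degrading enzyme heme oxygenase-1, rose 45.3-fold. SLC7A11 (ENSG00000151012), the cystine importer, rose from 79.9 ± 6.5 to 3432 ± 881, or 41.5-fold. The proliferation marker MKI67 (ENSG00000148773) dropped from 8189 ± 48 to 1224 ± 542. By the means of log2 values controls were 7.28-fold higher, while the authors' log2 ratio of the group means was -2.74.

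Of the 3511 listed genes, 3312 passed the limma test (adjusted p under 0.05), 1745 higher in fasting medium (52.7%) and 1567 lower. At least 2-fold changes numbered 934 higher and 696 lower. The authors' deposited table has 1764 higher and 1747 lower. In all 3511 listed genes the 3 values of one group lay beyond those of the other, which chance alone would give for 10% of unselected genes. Without fasting replicate 3, 3509 genes passed, among them all 3312. With edgeR scaled to the total reads of the listed genes, a part of each library, 2602 genes passed, 868 higher (33.4%) and 1734 lower. That scaling moves every log2 fold change by -0.48 and RLE scaling by 0.20. The listed genes cannot decide between these scalings, and changes are relative to the size factors of the authors.

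Rises and falls were ranked among called protein-coding genes with a mean of at least 100 normalized counts in the higher group. Genes below that minimum, such as CRYAB (log2 fold change 6.33), were not ranked. The other largest rises so ranked were ZFAND2A (42.3-fold), a proteasome-associated arsenite-inducible gene, the matrix metalloproteinases MMP10 (37.3-fold) and MMP1 (22.1-fold), and PTGS2 (33.2-fold), which encodes cyclooxygenase-2. CHAC1, which degrades glutathione, rose 30.6-fold and the immediate early gene FOS 25.5-fold. THBS1 rose 21.5-fold, GADD45B 21.1-fold and GADD45G 20.9-fold. Adjusted p values (limma, Benjamini-Hochberg) of these 12 rises ran from 1.85e-06 for HSPA6 to 5.10e-04 for GADD45G. Falls were smaller. After MKI67 came AKAP5 (log2 fold change -2.49), NEURL1B (-2.41), RASSF5 (-2.40), the nuclear lamina gene LMNB1 (-2.38), MYB (-2.37), KIF18B (-2.26), cyclin A2 (CCNA2, -2.19), OAS3 (-2.18), E2F2 (-2.17), BUB1B (-2.14) and ASPM (-2.12). MKI67, ASPM, BUB1B and OAS3 were among those that lay lower in fasting replicate 3 than in the other fasting libraries, MKI67 at 601 against 1582 and 1491 normalized counts. All 24 genes passed without that library too. The order of these falls then changed, with MYB at -2.49, AKAP5 at -2.42 and MKI67 at -2.41.

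**Figure D2:**
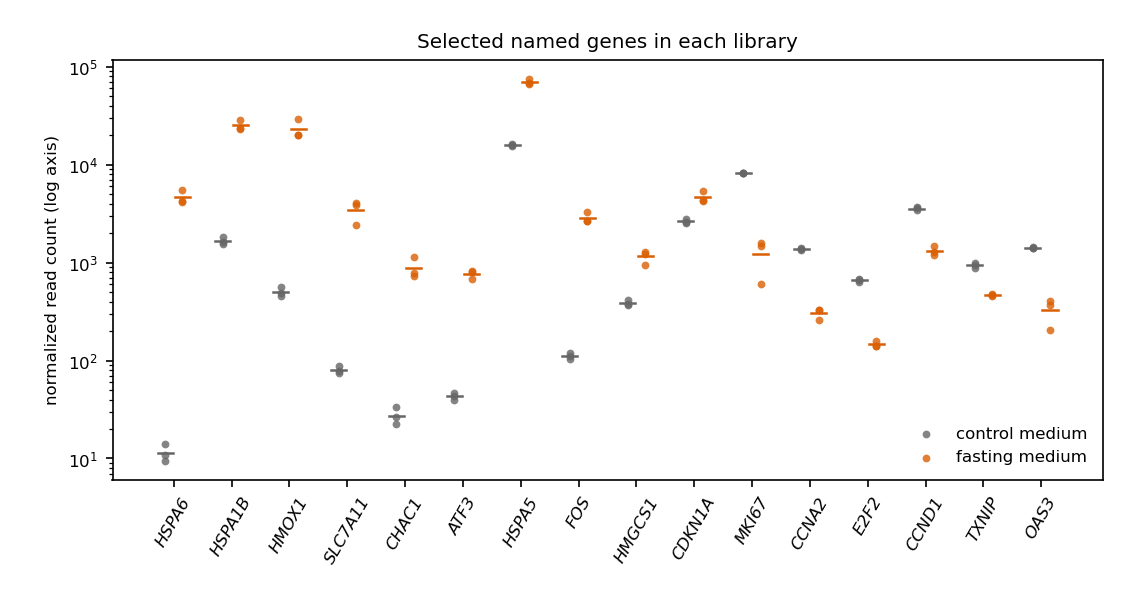
Normalized read counts (vertical log axis) of 16 named genes in the 3 control (grey) and 3 fasting libraries (orange), with the group mean as a bar. The groups do not overlap for any of the genes shown, and HSPA6 has the widest gap, from 11.5 to 4617.

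Counts for gene lists are given below as members that rose or fell among the listed ones, and unlisted members have no value here. Adjusted over the list alone, which could use listed members only, the number of members past the threshold was 29 for G1/S genes and 13 for ferroptosis promotion and otherwise the same as given. List p-values are from camera with adjustment over 30 lists, and the estimated-correlation p follows each. With the preset correlation 18 lists passed, and with an estimated correlation 0 did, the lowest adjusted p being 0.0502. Of the 333 called list members, 53 lost their call on leaving out at least 1 library, 20 with the trend with transcript length removed, 71 with total-read scaling and 17 with RLE scaling. Calls of genes named below that were lost in these ways are given with them. Without moderation of the variance, which was estimated on selected genes, ASPM, FTL, TFRC, PCBP1, CPT1A, HADH, HADHB, PC, MT-ATP8, PIK3R4, UTP20, RPL3, RPL4, PSMD3, STAT2, SP5 and H2AC20 among the genes named by rule did not pass (adjusted p = 0.0536 for PCBP1 to 0.271 for TFRC).

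Total-read scaling lowered the number of members past the threshold upward in most lists. Among the lists past camera, risers numbered 24 against 26 for ATF4 genes, 14 against 18 for the unfolded protein response, 7 against 11 for tRNA synthetases, 10 against 12 for NRF2 targets and 15 against 15 for heat shock. They numbered 9 against 13 for cholesterol synthesis, 11 against 13 for lysosome and 6 against 14 for autophagy genes (median 0.42). For ferroptosis they were 8 against 10 in defence and 6 against 12 in promotion (median 0.55). The p53 targets had 6 against 9, serum response genes 10 against 14, NF-kappaB genes 6 against 11 (median 0.66), ribosomal proteins 5 against 9 (median 0.50), the stress and RNA quality list 7 against 10 and interferon genes 0 against 1. Among the other lists, glycolysis had 1 riser and 2 fallers (median 0.11), iron handling 3 and 2 (median 0.10), ribosome biogenesis 2 and 2, hypoxia 5 and 4, apoptosis 2 and 3, histones 2 and 2, and fatty acid synthesis 0 and 6. RLE scaling, which moves values up, lowered the number of fallers instead. Fallers numbered 3 against 6 for CDK inhibitors (median -0.42, with 4 risers), 2 against 4 for hypoxia (median 1.02, with 7 risers), 6 against 8 for nucleotide synthesis, 2 against 3 each for ERK output, apoptosis and fatty acid oxidation, and 1 against 2 for iron handling. They numbered 0 against 1 each for autophagy, ribosome biogenesis and proteasome genes, 27 against 28 for G1/S and 24 against 26 for G2/M genes, and ferroptosis promotion had 13 risers against 12.

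Proliferation genes fell in both phases. Of 32 G1/S and DNA replication genes 29 were listed, and 28 fell, with a median log2 fold change of -1.18 (adjusted p = 2.05e-07, and adjusted p = 0.0502 with an estimated correlation). E2F2, an S-phase transcription factor, fell by 2.17, the checkpoint adaptor CLSPN by 2.05, CHAF1A, a chromatin assembly factor subunit, by 1.70 on the log2 scale. The helicase subunit MCM4 (-1.55) fell too. TK1, the remaining listed member, had a log2 fold change of -0.56 (adjusted p = 0.0965). Of 32 G2/M and mitosis genes 26 were listed and all 26 fell (median -1.67, adjusted p = 2.42e-07, and adjusted p = 0.0502 with an estimated correlation). Examples are CCNA2, the mitotic kinases AURKA (-1.66) and PLK1 (-1.89), and TOP2A (-1.95). The G2/M median lay 0.49 log2 units further down than the G1/S median, shown by a difference of -0.57, -0.42 and -0.45 in fasting replicates 1, 2 and 3 (SD 0.08). That difference was -0.33 once the trend with transcript length was removed. It was not tested across genes.

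Among 19 CDK inhibitors, pocket proteins and G1 cyclins, 4 rose and 6 fell (median -0.63, mean -0.15, adjusted p = 0.628, and adjusted p = 0.649 with an estimated correlation; fry gave the opposite direction). The CDK inhibitor CDKN1A rose (0.81, adjusted p = 2.14e-03) and so did CCNG2 (1.36). Cyclin D1 (CCND1) fell by 1.44 and CDK6 by 1.30 on the log2 scale. CDKN1B was not listed. All 9 listed of 26 p53 target genes rose (median 0.97, adjusted p = 4.04e-03, and adjusted p = 0.109 with an estimated correlation), led by SESN2 (3.32), GADD45A (1.97) and PLK2 (2.51). Of these 9 genes 4 belong to another list as well.

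Genes induced by the transcription factor ATF4 in amino acid stress formed the list with the most risers. Of 34, 26 were listed and all rose, with a median of 2.01 (adjusted p = 2.05e-07, and adjusted p = 0.109 with an estimated correlation). ATF4 itself rose by 2.13, ATF3 by 4.13, the pseudokinase gene TRIB3 by 3.20, and ASNS, asparagine synthetase, by 2.94 log2 units. SESN2, an inhibitor of mTORC1 signalling, went from 537 ± 45 to 5373 ± 157 normalized counts. Cytosolic aminoacyl-tRNA synthetases rose in all 11 listed of 20 (median 1.42, adjusted p = 3.61e-04, and adjusted p = 0.0897 with an estimated correlation), WARS1 by 1.97 and AARS1 by 1.82. In the unfolded protein response of the endoplasmic reticulum, 18 of 22 genes were listed and 18 rose (median 1.26, adjusted p = 3.66e-05, and adjusted p = 0.0897 with an estimated correlation). HERPUD1 rose by 3.34 and the chaperone HSPA5 by 2.14, from 15843 ± 380 to 69907 ± 4061 normalized counts.

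In the heat shock list 15 of 16 genes were listed and 15 rose (median 1.47, adjusted p = 3.66e-05, and adjusted p = 0.299 with an estimated correlation). The stress and RNA quality list, which shares HSPA1A and HSPA1B with it, moved the same way (median 2.60, 10 of 10 listed). HSPA1B rose by 3.91, HSPH1 by 2.94, DNAJB1 by 3.09 and the co-chaperone BAG3 by 2.74. HSPA1A and HSPA1B are near-identical copies, as HSPA6 and the pseudogene HSPA7 are close ones, and how reads were divided between them is uncertain. NRF2 target genes, which act in antioxidant defence, rose in 12 listed of 28 (median 1.94, adjusted p = 3.44e-04, and adjusted p = 0.109 with an estimated correlation). GCLM, a subunit of the enzyme that makes the glutathione precursor, rose by 2.73, thioredoxin reductase TXNRD1 by 2.15, and OSGIN1 by 3.86.

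Most listed members of both ferroptosis lists rose. In the defence list 10 genes rose and 1 fell among 11 listed of 27 (median 1.38, adjusted p = 4.86e-03, and adjusted p = 0.1004 with an estimated correlation). Apart from SLC7A11 and GCLM, its risers include SLC3A2 (3.29), the partner chain of the cystine importer, and ferritin light chain (FTL, 1.80). The acyltransferase gene MBOAT1 fell by 1.87. Of the 11 called members 8 also stand in the ATF4, NRF2, heat shock or lipid synthesis lists. GPX4, AIFM2 and FTH1 were not listed. In the promotion list 12 of 13 listed genes rose, of 26 members (median 1.00, adjusted p = 7.87e-04, and adjusted p = 0.0897 with an estimated correlation). HMOX1, PTGS2 and CHAC1 are often read as markers of the process, and SAT1, a polyamine acetyltransferase, rose by 3.18. Of the 12 called members of this list 2, HMOX1 and CHAC1, also stand in the ATF4, NRF2, heat shock or lipid synthesis lists. The transferrin receptor TFRC rose by 0.54 (adjusted p = 0.0417), a call lost on leaving out any single library except fasting replicate 3 (adjusted p = 0.144 to 0.176). ACSL4, which activates polyunsaturated fatty acids, had a log2 fold change of 0.56 (adjusted p = 0.0508), and without fasting replicate 3 it was 0.74 with adjusted p = 3.27e-08. ACSL4 passed in 11 of 24 settings, that one included. Others were the replicate block (limma, adjusted p = 0.0420) and edgeR with the authors' size factors (adjusted p = 0.0348). In iron handling 5 genes rose, including NCOA4 (0.93), the ferritin autophagy receptor, and 2 fell, PCBP1 (-1.08) and GLRX5 (-0.77), of 7 listed among 21 (median 0.56, adjusted p = 0.435, and adjusted p = 0.5798 with an estimated correlation). The call of GLRX5 was lost on leaving out any library except fasting replicate 3 (adjusted p = 0.0802 to 0.111) and with RLE scaling (adjusted p = 0.0912). FTL lay at 92443 normalized counts in fasting replicate 3 against 46918 and 50957 in the other fasting libraries.

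Cholesterol synthesis genes rose in all 13 listed of 25 (median 1.16, adjusted p = 4.86e-04, and adjusted p = 0.0897 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 385 ± 27 to 1154 ± 179 normalized counts, MSMO1 by 1.67 and HSD17B7 by 1.71 log2 units. Fatty acid synthesis went both ways, with 2 rising and 6 falling among 8 listed of 16 (median -0.71, adjusted p = 0.265, and adjusted p = 0.587 with an estimated correlation). ACSL3 rose by 0.73 (0.26 and not past the threshold with total-read scaling), and the desaturases FADS1 (-1.79) and FADS2 (-0.86) fell. Of 22 fatty acid oxidation genes 4 were listed, too few for the list test. HADHB rose by 0.62, while CPT1A (-0.62), HADH (-0.65) and PDK4 (-1.83) fell. HADHB lost its call without control replicate 3 (adjusted p = 0.0548) and with total-read scaling (0.14), and CPT1A with RLE scaling (-0.41). PDK4 lost its call without any 1 control library or fasting replicate 1 (adjusted p = 0.0806 to 0.160).

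Glucose transporters rose, SLC2A3 by 1.92 and SLC2A1 by 0.73, while the lactate exporter SLC16A3 (-0.95) and lactate dehydrogenase LDHA (-0.59) fell. In the glycolysis list 4 rose and 2 fell of 6 listed among 19 (median 0.58, adjusted p = 0.465, and adjusted p = 0.581 with an estimated correlation), and HK2 was not listed. With total-read scaling the rise of SLC2A1 no longer passed (0.26), and neither did those of MYC (0.11) and TFRC (0.10). Hypoxia response genes split, 7 rising and 4 falling of 11 listed among 22 (median 0.82, adjusted p = 0.295, and adjusted p = 0.417 with an estimated correlation), VEGFA by 1.84 and P4HA2 by 1.58 upward and CA9 by -1.47. None of 50 nuclear-encoded oxidative phosphorylation genes was listed. Of 25 tricarboxylic acid cycle and related genes 2 were listed and rose, PCK2 (1.75) and PC (0.93, not past the threshold with total-read scaling, 0.44). Of 13 mitochondrially encoded messenger RNAs MT-CO1 rose by 0.70 and MT-ATP8 (-1.09) fell. MT-CO1 lost its call without control replicate 2 or 3 (adjusted p = 0.0702 and 0.0635), with total-read scaling (0.22) and with the length trend removed (0.34, adjusted p = 0.0856). TXNIP, which is induced by glucose, fell by 0.99 on the log2 scale.

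Autophagy genes rose in 14 and fell in 1 of 15 listed among 30 (median 0.85, adjusted p = 3.24e-03, and adjusted p = 0.0899 with an estimated correlation). MAP1LC3B, which encodes an LC3 protein of autophagosome membranes, rose by 2.05, GABARAPL1 by 1.80 and the cargo receptor SQSTM1 by 1.60, and PIK3R4 (-0.70) fell. The call of PIK3R4 was lost without any 1 control library (adjusted p = 0.0821 to 0.0982) and with RLE scaling (-0.48). Lysosome genes rose in all 13 listed of 34 (median 1.24, adjusted p = 3.44e-04, and adjusted p = 0.179 with an estimated correlation), the proton pump subunit gene ATP6V1B2 by 1.43. FOXO target genes went both ways, 7 up and 4 down of 11 listed among 24 (median 1.24, adjusted p = 0.463, and adjusted p = 0.5798 with an estimated correlation). IRS2 rose by 2.03 and ERBB3 (-1.76) fell.

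Among genes of serum response factor and YAP, 14 rose and 2 fell of 16 listed among 29 (median 1.46, adjusted p = 2.39e-03, and adjusted p = 0.0897 with an estimated correlation). FOS, FOSB (2.36) and CCN2 (2.63) rose, and ACTB, cytoplasmic beta-actin, fell by 0.82 and FLNA by 0.95 on the log2 scale. FLNA did not pass without control replicate 3 (adjusted p = 0.0603). ANKRD1 had no control read, and placing it at its bound leaves this median in place. ERK pathway output genes split into 5 rising, among them SPRY2 (1.81) and EGR1 (1.43), and 3 falling, of 8 listed among 17 (median 0.90, adjusted p = 0.465, and adjusted p = 0.5798 with an estimated correlation). NF-kappaB and inflammatory genes rose in all 11 listed of 22 (median 1.14, adjusted p = 6.33e-03, and adjusted p = 0.379 with an estimated correlation), CXCL8 from 5.78 ± 2.44 to 95.1 ± 18.8 normalized counts and LIF by 0.75 (0.27 and not past the threshold with total-read scaling). In this list fasting replicate 3 lay a median of 0.47 log2 units above the other fasting libraries. Interferon-stimulated genes fell in 7 and rose in 1 of 8 listed among 31 (median -1.24, adjusted p = 0.0367, and adjusted p = 0.165 with an estimated correlation). IFIT1 (-1.86), IFIH1 (-1.55) and OAS3 fell and STAT2 rose by 0.58. STAT2 lost its call on leaving out any library except fasting replicate 3 (adjusted p = 0.0507 to 0.0695) and with total-read scaling (0.12). Without fasting replicate 3 the list had a larger fall (median -1.39) with the same numbers of 7 falling and 1 rising, yet did not pass against the other listed genes (adjusted p = 0.050006). It did not pass among genes of at least 50 normalized counts either (adjusted p = 0.0931).

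Ribosomal protein genes were listed in 9 cases of 69 and all 9 rose (median 0.96, adjusted p = 0.0289, and adjusted p = 0.5798 with an estimated correlation), RPL3 by 0.96 and RPL4 by 0.92. Fasting replicate 3 lay 0.65 log2 units above the other fasting libraries in this list, the median was 0.78 without it (camera adjusted p = 2.78e-03), and after removal of the trend with transcript length 6 rose and adjusted p was 0.0741. Several of these genes have pseudogenes that share reads. MYC rose by 0.59 (adjusted p = 4.19e-03). The list of ribosome biogenesis genes also holds MYC itself and HSPD1, a member of the heat shock list. In it 4 rose, RRP12 (0.99), HSPD1 (1.00) and MYC among them, 1 fell (UTP20, -0.75) and 1 did not pass, of 6 listed among 32 (median 0.66, adjusted p = 0.435, and adjusted p = 0.5798 with an estimated correlation). Of its called members 2, MYC and HSPD1, also stand in another list. The fall of UTP20 was -0.10 (adjusted p = 1.00) with the length trend removed, and its call was lost without any 1 control library (adjusted p = 0.0974 to 0.137), with RLE scaling (-0.51) and with DESeq2 scaled by itself (adjusted p = 0.0782). Nucleotide synthesis split into 4 risers, led by MTHFD2 (1.72), and 8 fallers such as RRM2 (-1.07), of 12 listed among 25 (median -0.62, adjusted p = 0.379, and adjusted p = 0.483 with an estimated correlation). Of 31 proteasome genes PSMD3 (-0.52) alone was listed, and it fell, a call lost on leaving out any library except fasting replicate 3 (adjusted p = 0.0574 to 0.0865), with RLE scaling (-0.31, adjusted p = 0.118) and with DESeq2 scaled by itself (adjusted p = 0.0649). Of 25 replication-dependent histone genes 6 were listed, with H2BC12 (1.59) and 3 others rising and H2AC20 (-2.14) and H1-2 (-1.18) falling (median 1.14, adjusted p = 0.484, and adjusted p = 0.649 with an estimated correlation). Histone genes share reads, and fasting replicate 3 lay 0.40 above the other fasting libraries in this list. With the length trend removed 1 histone gene rose and 2 fell, H2BC12 was at 0.27 (adjusted p = 0.496), and camera pointed down (adjusted p = 0.982). H1-2 lost its call on leaving out any library except fasting replicate 3 (adjusted p = 0.0567 to 0.0951).

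Wnt target and stem cell genes changed in 6 cases of 22, with 4 falling, including SP5 (-1.79) and AXIN2 (-0.96), and CD44 (1.12) and MYC rising (median -0.93, adjusted p = 0.497, and adjusted p = 0.581 with an estimated correlation). Of 27 apoptosis genes 7 were listed. PMAIP1 (2.09) and BBC3 (1.21), which promote cell death, rose with 2 others, and BCL2 (-0.95), CASP6 (-0.85) and APAF1 (-1.02) fell (median 0.69, adjusted p = 0.720, and adjusted p = 0.731 with an estimated correlation). APAF1 lost its call without any 1 control library (adjusted p = 0.112 to 0.144), with RLE scaling (-0.75) and with the length trend removed (-0.52, adjusted p = 0.0505). Of markers of other cells that a pure culture should lack, 0 of 14 fibroblast genes and 1 of 14 blood cell genes were listed. The latter, CD14, rose from 0.808 ± 0.155 to 8.08 ± 0.40 normalized counts. Other cells present alike in both media would leave their markers unlisted, so these counts do not test purity. In a list of stress and RNA quality genes, all 10 listed of 13 rose (median 2.60, adjusted p = 3.44e-04, and adjusted p = 0.0897 with an estimated correlation), among them DUSP1 (2.84), MALAT1 (0.59) and NEAT1 (0.56). With total-read scaling MALAT1 (0.13) and NEAT1 (0.09) did not pass. Since 7 of these 10 stand in other lists, they are not separate evidence.

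**Figure D3:**
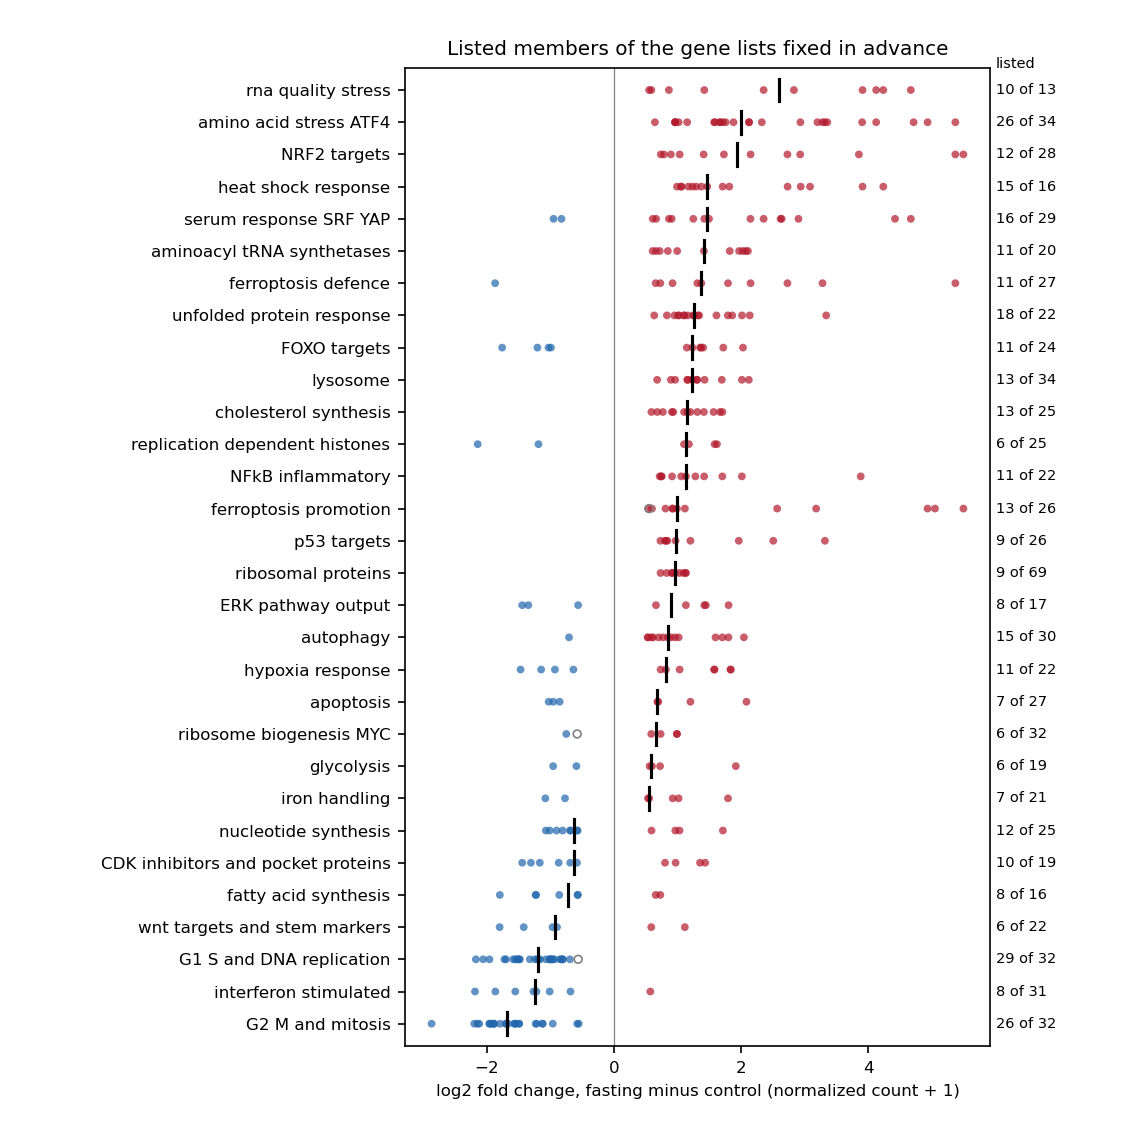
Log2 fold change (horizontal axis, fasting minus control) of listed members of the lists with at least 5 listed members. Each point is a gene, red higher and blue lower when past the threshold and open grey when not, black bars are medians, and numbers give listed and all members; the medians run from -1.67 for G2/M genes to 2.60 for the stress and RNA quality list.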

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

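No gene named by the rule changed direction in 24 settings. Leaving out a library or changing the pseudocount, filter, moderation or block could not turn a direction, since groups never overlapped in listed genes. Of the values of genes named by the rule under these settings, 2201 stayed on their side of the threshold, 88 no longer passed and 11 passed newly. The alternatives chosen after seeing the data were the filter at 50 normalized counts, no moderation, the authors' size factors and TMM in edgeR, the authors' size factors in DESeq2, and both removals of a length trend. Against the 3312 genes called (1745 higher, 1567 lower; 333 list members), a minimum change of 1.5-fold gave 1012 (637 higher, 375 lower, 178 list members), by construction a stricter test. Without moderation, where each gene has 4 residual degrees of freedom, 1981 passed (1134 higher, 847 lower). Scaling to total reads of listed genes left 868 higher, a shift of the scale. The G2/M minus G1/S difference became -0.33 with the length trend removed from every library, and the cause was not tested. Of 30 lists 18 passed, 0 with an estimated correlation, 29 with directional fry and 30 with mixed fry, neither of which compares a list with other genes. Both fry tests ran on members the authors had already called in this comparison, so their passing is no separate support. Other settings kept 17 or 18 of the 18 list calls. Count tests on recovered reads called 3347 (edgeR, the authors' size factors), 3482 (DESeq2, the same), 3107 (DESeq2, its own), 2983 (edgeR with RLE, 59.0% higher) and 3399 genes (limma-voom). Pseudocounts of 0.1 and 0.01 gave 3243 and 3171 genes, the filter at 50 gave 2911, and thinning gave 3235.

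Leaving out 1 library gave 2624 to 3509 genes, 1464 to 1762 higher and 1160 to 1747 lower, 285 to 336 list members, 17 to 18 lists, and a G2/M minus G1/S difference of -0.51 to -0.44. The replicate block gave 3293 genes, 3227 of them shared, and 18 lists. Nothing in the labels pairs the numbers, and the deviations of same-numbered samples correlated at 0.0456, 0.0235 and 0.0798. Not every sample correlated best with its own number (control replicate 1 with fasting replicate 2, 0.0907). The filter at a mean of 5 CPM and the shares of mitochondrial and ribosomal counts, with and without the 10 most abundant genes, were not run, because they need library totals. Depth limits low genes, where 1 read is worth 0.710 to 1.38 normalized counts.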

Other observations

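All tests of explanations in this part were chosen after the results were seen.

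The RNA classes counted here other than protein-coding genes were mostly higher in fasting medium, and further classes were not counted. Of the called protein-coding genes 48.9% rose (1420 of 2901), against 90.7% of processed pseudogenes (78 of 86), 86.6% of lincRNAs (71 of 82) and 73.3% of antisense genes (63 of 86). With the trend with transcript length removed these shares were 50.2%, 71.4% (30 of 42), 83.1% (54 of 65) and 63.6% (42 of 66). Host genes of small nucleolar RNAs rose in 8 of 9 cases. Short transcripts lay higher in fasting replicate 3, and without that library SNHG8 stood at 1.51 log2 units against 1.80, SNHG7 at 1.47 against 1.77 and GAS5 at 1.12 against 1.39. With the length trend removed they stood at 0.84, 1.48 and 1.06. SNHG10 (-1.44) fell. The translation factors EEF1A1 (1.03), EEF2 (1.00) and EEF1B2 (1.02, and 0.41 with the length trend removed) rose. The mitochondrial ribosomal RNA MT-RNR2 went from 18755 ± 393 to 76112 ± 15867 normalized counts and MT-RNR1 rose by 1.65 (0.92 with the length trend removed). EEF1A1 and many processed pseudogenes share reads with their parent genes or copies, so their division is uncertain. Expression level was not matched between classes, so part of these shares may come from low counts. Among listed genes 41 had no control read and 1 had no fasting read. Of all called genes 52.7% rose, against 50.6% with the filter at 50 normalized counts. These classes and genes were chosen after their values were seen, and no test was made between classes.

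In 41 genes no control library held a read. Against a floor of 3 reads over the control group (0.790 normalized counts, counting error only), the small heat shock gene CRYAB was at least 105-fold higher in fasting medium, at 83.1 ± 31.6 normalized counts (SD, n = 3), and the hexokinase-domain gene HKDC1 at least 28.2-fold higher. HSPA7, a pseudogene close in sequence to HSPA6, was at least 58.9-fold higher, and the division of reads between them is uncertain. A single gene, GPRIN3, had no fasting read.

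Fasting replicate 3 stood apart from fasting replicates 1 and 2. The same response further advanced, as the whole cause, would place risers higher there at every length, but 210 risers with the longest transcripts lay at a median of -0.249 log2 units (interval -0.328 to -0.171) and 250 fallers with the shortest at 0.374. A part played by it stays open, since across all lengths the difference of fasting replicate 3 from replicate 1 correlated with the response in replicate 2 at 0.0955 (interval 0.0535 to 0.133), and that from replicate 2 with the response in replicate 1 at 0.0926. GC content is argued against as the source of the length trend, since the correlation with length stayed at -0.708 once GC trends were removed. Apart from that trend, a part played by GC content stays open. With length trends removed, the difference of fasting replicate 3 correlated with GC content at 0.240 (interval 0.206 to 0.275). Loss of reads from long transcripts in that library stays open, because the correlation of -0.722 with length is the pattern itself and no separate test.

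The 52 listed members of the heat shock, NRF2 and ATF4 lists had a median log2 fold change of 1.75. Read loss in fasting replicate 3 is argued against as the whole cause, since the median was 1.64 without that library. Scaling moves all genes alike, which argues against it as the source of the gap to the G1/S and G2/M lists (medians -1.18 and -1.67). As a source of part or all of the rise itself, scaling is not settled. The median of the 52 genes was 1.26 or more under 4 other scalings, but these were formed from the listed genes alone. They moved values by only -0.48 to 0.20, so a larger shift was not tried. Handling at harvest stays open, because medium and handling are the same groups, and 10 of 13 genes of the stress and RNA quality list rose. The rise may be a response to the medium, a hypothesis that these libraries cannot separate from handling. HMOX1 and SLC7A11 lie in this set, and HSPA6 stands in none of the fixed lists.

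Long transcripts fell more often than short ones. Of the listed genes with the shortest transcripts 60.7% were higher in fasting medium, and of those with the longest 29.8%. The gap was 30.9 percentage points (30.89) outside every list. The fixed lists held too few of these genes to make the gap, as 617 of the 723 shortest and 669 of the 722 longest lay outside. Removing them could thus hardly change it. Stress or cell cycle genes in no fixed list were not removed, so a part played by such genes stays open. Loss of reads in fasting replicate 3 alone stays open, because listing used that library, and among genes changed at least 2-fold in fasting replicates 1 and 2 the gap was 13.2 points (interval 4.67 to 21.4). Among those changed at least 4-fold there it was 21.1 points (interval -2.86 to 45.1). Lower RNA integrity in all fasting libraries stays open too, as the correlation of -0.113 with length in fasting replicates 1 and 2 covers called genes alone.

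Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 3312 genes, and the highest of the others called 2. The splits are too few for a share under 0.05, and the listed genes were chosen on the real split.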
